A study of Homo sapiens with 6 samples.

How the data were processed

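RNA of exosomes from erastin-resistant and parental SNU-668 cells was measured on 1 array per sample, 3 samples per group. Per the labels' protocols, cells were grown in medium with 10% serum, then kept for 48 to 72 h in medium without supplements. That medium was cleared by centrifugation and passed through a 0.22 µm filter. Vesicles were then isolated with a precipitation reagent or by ultracentrifugation; which sample had which is not given in the sources used here. Cy3-labelled cRNA was made from 0.5 µg RNA. Groups and replicate numbers come from the sample titles.

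The scanner files hold an intensity per spot, which per the file headers was extracted with Agilent Feature Extraction 11.0.1.1; the submitters' processing notes name version 9.1 of that software, and the cause of the difference is not known. Per the file headers the processed intensity is background-subtracted, and dim spots carry a small surrogate value in place of a signal. No normalization between arrays was applied to these intensities. The deposited series table holds values on a log2 scale. Its scale and normalization are not stated; across the 26505 tested probes that matched by probe name, each column correlated with the log2 scanner values of its own array at r = 0.998 to 0.9995, so the scale is taken as log2 and no centring of genes was seen. How its columns were normalized is not stated. Their medians were 2.80 for the 3 resistant samples and for parental 1 and 2, and 2.36 for parental 3, and each column had the same maximum of 16.36. A shared maximum is what quantile normalization gives, so the deposited values and that setting may not be separate alternatives. The table served as an alternative only. The values are levels and not ratios, so no direction had to be settled.

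The header names genome build hg19 for the array design. Probe names are the array maker's own, and the files pair them with no gene. The exceptions are 20 probes with RefSeq accessions, 10 spots each, of which 20 matched a gene symbol through the RefSeq table of assembly GRCh38.p14. Because the builds differ, no coordinates are given. The gene names of the other probes are not used here.

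The main values were log2 processed intensities minus each array's 75th percentile, spots of a probe averaged on the log2 scale. Fewer probes were detected than not, so the percentile was taken over the 20245 probes well above background on all 6 arrays. This left all-probe differences with a median of 0.12; it was 0.22 with normexp, -0.11 with quantile normalization, -0.24 with the percentile over all probes and -0.43 with the array median, so differences are relative to those shifts. Control spots (68 control probes and 60 negative ones) and spots flagged as outliers were left out; the outlier flags removed a further 73 probes. A probe counted as detected on an array when at least 50% of its spots were flagged well above background. Probes detected on at least 3 of 6 arrays were tested, 26521 in all, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The array's 75th percentile of detected probes stood at 526 to 946 times its negative probes. Those negative probes stood at 2.12 to 3.17 after background subtraction, under the lowest detected signals of 8.78 to 13.6, where spots can carry surrogate values. The ratio may therefore not be one over a measured background. The design, the alternatives and 25 gene lists were fixed before the data were examined; alternatives and tests added later are named in the closing section.

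The rule for named items took the probes past the threshold with the highest and lowest differences, the probes with the smallest p where fewer than 5 passed in a direction, members of the fixed lists, and a set of ferroptosis and vesicle genes if measured. Without gene names it was applied to probe identifiers, 2 per direction. Of the 20 genes that could be named, 18 are given one by one; the other 2 are not reported here, and 1 of them was tested and enters the panel's counts and set tests. Tests of list shifts and separate counts of long non-coding and mRNA probes were not run, because they need a gene or class for each probe. The 17 tested genes of the panel were tested as a set with camera and fry, a step chosen after the data were seen.

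Per the file headers, 4 arrays (parental 1, 2 and 3 and resistant 1) lay on one slide and 2 (resistant 2 and 3) on another, so slide was tried as a block. The other alternatives were normexp background correction with an offset of 50, run on the median spot signal because the files hold no mean signal, quantile normalization, other scaling points, no detection filter or a stricter one, the replicate number as a block, a trended and robust variance, array weights, a plain t-test per probe, the deposited table, and leaving out each sample. Also not run were a mean over a gene's probes and an estimated correlation for the gene lists. For single genes and probes, slide as a block, the deposited table and scaling to the array median or to the percentile over all probes were added after the data were seen.

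Data were simulated with the spread of these 26521 probes and 200 changed ones. The fit recovered 0% of changes of 1 and of 2 on the log2 scale, 59% of changes of 4 and 83% of changes of 6. It made 0, 0, 5 and 9 false calls, and it called 0 probes when none was changed. The simulated noise was independent between probes and samples, with no surrogate values and no slide effect. The rate of false calls in the real data may therefore differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.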

Results

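SNU-668 is an established human gastric cancer cell line. Erastin is a small molecule that blocks cystine import through system xc- and so triggers ferroptosis, an iron-dependent cell death driven by lipid peroxidation. The series asked how the RNA of exosomes, and long non-coding RNA above all, differs between a derivative of this line that resists erastin and the parental line. Exosomes are small vesicles that cells release into their medium. RNA from exosomes of resistant cells (n = 3) and of parental cells (n = 3) was hybridised to 6 single-colour arrays, described as long non-coding RNA arrays, which also hold probes named by mRNA accession. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

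After control probes and probes flagged as outliers were left out, 60851 probes remained on each array. In resistant samples 1, 2 and 3, 42.7%, 42.2% and 46.9% of them were well above background, and in parental samples 1, 2 and 3 the shares were 40.9%, 47.7% and 40.1%. The group means were 43.9% ± 2.59 and 42.9% ± 4.19 (SD, n = 3 each), a difference of 1.05 percentage points (exact 2-sided permutation test, p = 0.6, where 0.1 is the smallest p that 3 against 3 allows; 0.6 after Benjamini-Hochberg adjustment over the 3 sample-level comparisons). That difference was -0.44 without resistant 3 and -0.34 without parental 3. It was 0.03 without parental 1, 1.67 without resistant 1, 1.91 without resistant 2 and 3.46 without parental 2. No probe was saturated, and 20245 probes were well above background on all 6 arrays. The number of arrays limits the precision of every value.

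Over the 26521 tested probes, Pearson's r across probes averaged 0.924 within groups and 0.905 between them, with ranges of 0.905 to 0.943 and 0.833 to 0.948; probes are not independent replicates. The most distant pair was resistant 3 and parental 1. The closest pair was resistant 1 and parental 3, which shared a slide; each was the other's nearest sample, and the nearest sample of the other 4 lay in their own group. On the first principal component, which held 44.1% of the variance, resistant samples 1, 2 and 3 stood at 4.21, 31.8 and 180 and parental samples 1, 2 and 3 at -145, -2.88 and -68.8, so the groups did not overlap, as happens by chance for 10% of such splits. Resistant 1 and parental 2 lay closer to each other there than either did to the rest of its group. No pair of arrays held identical values.

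Exosomes of resistant cells had a higher signal than those of parental cells at 95 of the 26521 tested probes (0.358%), and a lower signal at 0 (limma, adjusted p under 0.05; at an unadjusted p under 0.05 the counts were 1538 higher and 665 lower). All 95 were detected in every resistant sample, and 91 of them were not well above background in any parental sample; the other 4 were detected in 1 parental sample. For those 91 an approximate lower bound on the fold ran from 1.75 to 52.5, with a median of 10.8. Each bound sets the mean of the 3 resistant samples against the parental mean after each parental value was raised to the lowest detected signal of its array. That signal is no strict detection limit: ASHGV40009205, not detected in parental 3, stood there at -7.13, above the lowest detected -7.25. The bounds also leave out sampling error. The fitted differences ran from 2.91 to 7.28 on the log2 scale, with a median of 5.35, and rest on surrogate values for dim parental spots. With normexp background correction the same 95 differences had a median of 1.74 and ran from 0.68 to 3.40. That setting adds an offset of 50, above the lowest detected signals of 8.78 to 13.6 on the arrays. Such an offset by itself shrinks log2 differences that involve dim spots. The normexp values are therefore not the differences with surrogate values removed. The same holds for the normexp values of single dim probes and genes below. The files give the array maker's identifiers for these probes and no gene, so whether a long non-coding RNA or an mRNA rose is not known from the sources used here.

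ASHGV40036671 and ASHGV40056459 were picked by fitted difference, an order that depends on surrogate values, and another called probe had a higher bound than either. Both were above background in 3 of 3 resistant samples and 0 of 3 parental samples, so there is no parental level to give. By its approximate bound ASHGV40036671 was 36.9-fold higher, with a resistant mean of -2.14 ± 0.076 (log2 relative to each array's 75th percentile, SD, n = 3, limma adjusted p = 0.00177). ASHGV40056459 was 30.7-fold higher by its bound, with a resistant mean of -2.40 ± 0.79 (limma adjusted p = 0.00964). The fits, with surrogates on the parental side, gave 7.28 (SE 0.265) and 7.19 (SE 0.463), and with normexp 3.00 (adjusted p = 0.0499) and 2.92 (adjusted p = 0.148). ASHGV40056459 also missed the threshold with slide as a block (6.57), with the replicate number as a block (7.19) and without parental 1 (7.25) or parental 3 (7.29); ASHGV40036671 missed it with either block (7.37 and 7.28). On the lower side the smallest p values missed the threshold. ASHGV40057247 differed by -2.62 (SE 0.343, limma adjusted p = 0.0513; detected in 1 of 3 resistant and 3 of 3 parental samples; -0.58 with normexp), and ASHGV40028800 by -2.17 (SE 0.289, limma adjusted p = 0.0538; detected in all 6). Among all tested probes, 3512 (13.2%, where chance gives 10%) had groups that did not overlap, 2398 of them higher in resistant samples and 1114 lower.

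With slide as a block, a fit that compares resistant 1 with the 3 parental samples on slide 1, limma called 0 probes (1100 at an unadjusted p under 0.05), with a median difference of 4.95 over the 95 probes against 5.35 without the block and ASHGV40036671 at 7.37 (adjusted p = 0.12); slide 1 alone also gave 0 (968 unadjusted), and slide 2 held resistant samples only. The 95 probes had been picked with resistant 1 in the fit, so the median of 4.95 was largely fixed by that choice. Probes picked without resistant 1 had medians of 0.26 to 0.69 in resistant 1 minus the parental sample left out. Without the block, the count of called probes fell to 48, 18, 1 and 1 without resistant 2, parental 2, parental 1 and parental 3. It fell to 1 with normexp background correction (2469 at an unadjusted p under 0.05), and to 0 among the probes detected on all 6 arrays (1535 unadjusted). The loss of the 95 under that last filter was fixed in advance, since each was detected in at most 1 parental sample.

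**Figure D1:**
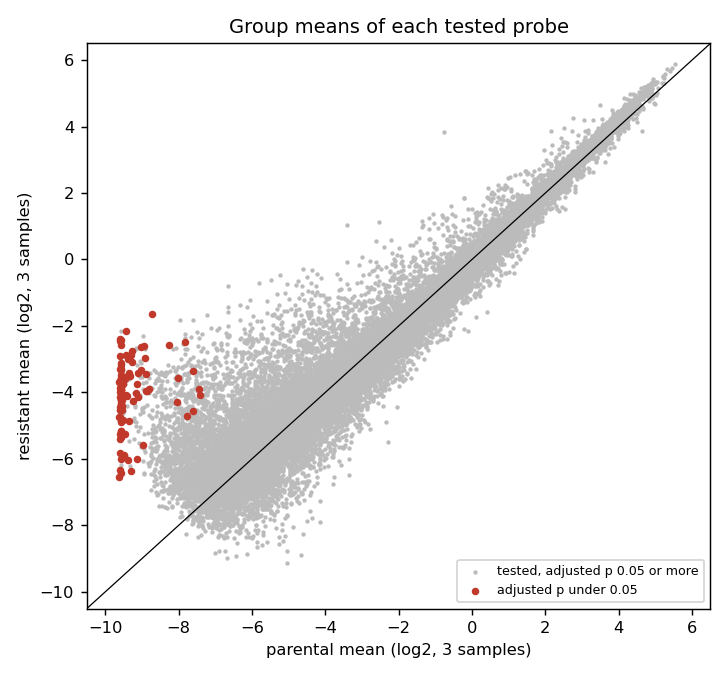
Mean log2 signal of each tested probe in 3 parental samples (horizontal axis) and 3 resistant samples (vertical axis), both relative to each array's 75th percentile over probes detected on all arrays, with the line of equal signal. The 95 probes with an adjusted p under 0.05 (red) lie at the low end of the parental axis, and 91 of them were not well above background in any parental sample.

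Genes could be named for 20 probes, which carry RefSeq accessions; many of them are common reference genes. Of these, 17 were bright enough to test: 15 had a higher mean in resistant exosomes and 2 a lower one, and 0 passed limma's test, whether adjusted over all probes or over the panel alone (2 had an unadjusted p under 0.05). The panel's median log2 difference was 0.86 and its mean 1.26, against a median of 0.12 over all tested probes. The panel's median was 0.31 without resistant 3, 0.32 without parental 1, 1.87 without resistant 2 and 0.31 with the array median. As a set the panel gave p = 0.0217 with camera at a preset correlation of 0.01, and p = 0.464 with an estimated correlation, which was 0.522. With slide as a block these p values were 0.0237 and 0.499 and the median difference was 1.025. The rotation test fry of limma, with the panel as its single set so that adjustment changes nothing, gave adjusted p = 0.346 for a shift in one direction and 0.327 for change in either.

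ODC1, the rate-limiting enzyme of polyamine synthesis, had the smallest p of the panel. Its log2 signal was -4.18 ± 0.65 in resistant and -8.34 ± 1.77 in parental samples (SD, n = 3 each), a difference of 4.16 (SE 0.897, limma adjusted p = 0.231 over all probes and 0.0509 over the panel). It was detected in 3 of 3 resistant samples and, of the parental ones, in parental 2 only. The size of the difference therefore rests in part on surrogate values for dim spots. With normexp, whose offset also shrinks dim differences, the difference was 1.44 (limma adjusted p = 0.248). Every resistant value lay above every parental one. With slide as a block the difference was 3.48 (adjusted p = 0.959).

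The glycolytic enzymes PGK1 and GAPDH had higher means in resistant exosomes and did not pass the test. PGK1 differed by 2.89 (SE 1.07, limma adjusted p = 0.548 over all probes, 0.0669 over the list alone). It was detected in 3 resistant samples and 1 parental sample, so the size of its difference too rests on surrogate values. With normexp, whose offset also shrinks dim differences, the PGK1 difference was 1.02 (limma adjusted p = 0.466). GAPDH differed by 1.88 (SE 1.28, limma adjusted p = 0.82, 0.188 over the list alone) and by 1.025 with slide as a block, with single samples from -3.17 in parental 1 to 3.13 in resistant 3. Control probes for the same genes gave differences of 1.21 for the 3' end of GAPDH and 1.81 for the 3' end of PGK1. Their SDs in resistant and parental samples were 1.69 and 1.25 for GAPDH and 1.60 and 2.00 for PGK1, and the groups overlapped for both. The 3' PGK1 control was detected in all 6 samples, unlike the panel's PGK1 probe, which was not well above background in parental 1 and parental 3.

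Among genes of the cytoskeleton, ACTB and ACTG1, the cytoplasmic actins, differed by 2.81 (SE 1.40) and 2.05 (SE 1.30), or 2.28 and 1.37 with slide as a block. The dynein light chain DYNLL1 differed by 0.86, which was 0.01 without resistant 3, 0.05 without parental 1 and 1.70 without resistant 2. ARHGDIA differed by 0.40, which was 0.03 without parental 1, 0.74 without resistant 2, 0.89 with slide as a block and -0.16 when each array was scaled to its median. PFN1, profilin, which binds actin monomers, went the other way at -0.52 (SE 0.384), which was -0.25 without parental 2, -0.16 with slide as a block and -1.08 with the array median. None of these 5 passed the test. ACTB ranged over 7.30 log2 units across the samples, from -5.41 in parental 1 to 1.89 in resistant 3, although its 3 resistant values all lay above the parental ones.

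In translation, the ribosomal protein genes RPLP1 and RPS18 differed by 2.38 (SE 1.45) and 1.39 (SE 0.725; 0.73 without parental 1), with adjusted p = 0.149 for each over the list alone and 0.783 and 0.717 over all probes (limma). The ribosome-bound scaffold RACK1 differed by 0.58 (SE 1.70), and was -0.86 without parental 1, -0.73 without resistant 3, 1.97 without resistant 2 and 0.03 with the array median. EIF3D, an initiation factor subunit, differed by 0.19 (SE 0.815), was -0.75 without resistant 3 and 0.83 without resistant 2, and turned to -0.19 with quantile normalization, -0.17 with the percentile over all probes, -0.36 with the array median and -0.41 with slide as a block. RPL10 was detected in 1 of 3 resistant and 0 of 3 parental samples and was not tested.

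Among the remaining genes, H3-3A, a replication-independent histone, differed by 0.78 (SE 0.406), which was 0.49 without parental 1 and 0.23 with the array median. MTX1, a mitochondrial outer membrane protein, differed by -0.29 (SE 0.29), which was -0.17 without parental 1 and -0.84 with the array median. COX4I1, a subunit of cytochrome c oxidase, differed by 1.02 (SE 1.62), which was 0.04 without parental 1, 2.77 without resistant 2 and 2.81 with slide as a block. PRMT1, an arginine methyltransferase, differed by 0.44 (-0.48 without parental 1, 1.56 without resistant 2 and 1.45 with slide as a block). Both were detected in 2 of 3 samples of each group, with resistant 2 and parental 1 the dim ones. The sizes of both differences therefore rest in part on surrogate values. With normexp, whose offset also shrinks dim differences, they were 0.71 for COX4I1 and 0.32 for PRMT1. PRMT1 was at -0.11 with array median scaling and -0.01 with quantile normalization. GRM4, a glutamate receptor, was detected in 1 resistant sample and was not tested.

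The panel's level differed more between samples of one group than between the groups. Its median per sample was -2.39, -3.56 and -0.90 in resistant samples 1, 2 and 3 and -5.19, -2.32 and -2.69 in parental samples 1, 2 and 3 (exact 2-sided permutation test of the group means, p = 0.5; 0.6 after Benjamini-Hochberg adjustment over 3 comparisons). Without parental 1, the differences of ACTB, RPLP1, ACTG1 and GAPDH were 1.21, 0.72, 0.63 and 0.71, and without both parental 1 and resistant 3 the panel's median difference was -0.07. The signal of the 3' GAPDH control over the 5' one, a measure of RNA integrity, was 2.67, 1.15 and 0.62 in the resistant and 2.66, 2.24 and 1.31 in the parental samples on the log2 scale. The group means of this GAPDH measure differed by -0.59 (exact 2-sided permutation test, p = 0.5, and 0.6 after the same adjustment). The same measure for PGK1 was 4.09, 6.23 and 5.84 in the resistant and 5.02, 5.48 and 4.22 in the parental samples. It ordered the samples otherwise: resistant 2 and 3 had the smallest differences by GAPDH and the largest by PGK1. In parental 1 the 5' PGK1 control was not detected.

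**Figure D2:**
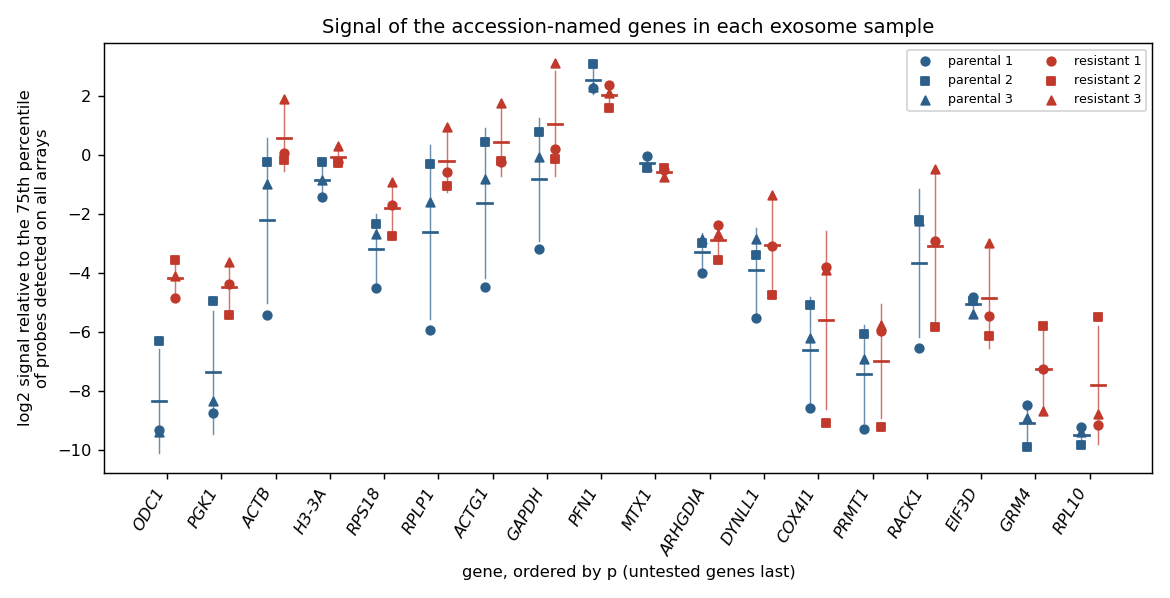
Log2 signal of 18 named genes in each sample, relative to each array's 75th percentile over probes detected on all arrays. Points are single samples (blue parental, red resistant), horizontal bars are group means and vertical lines are 1 SD (n = 3 each). Parental 1 is the lowest sample for ACTB at -5.41 and for GAPDH at -3.17, and resistant 3 is the highest for both at 1.89 and 3.13.

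Presence of signal, apart from its level, was compared as well. In all 3 resistant samples and no parental sample, 255 probes were well above background, and 119 were so in all 3 parental samples and no resistant one. Of the 95 called probes, 91 were among the 255. This follows from the filter, since a tested probe detected in no parental sample had to be detected in all 3 resistant ones. No test was run on these counts; another split of the same 6 samples, with resistant 1, parental 1 and parental 3 on one side, gave 42 probes detected only there and 350 only in the remaining samples. Without parental 3 the order turned, to 344 probes only in resistant and 524 only in parental samples.

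The question of ferroptosis genes could not be put to these files. Of 25 gene lists, 23 had 0 members among the 20 named genes, those for ferroptosis defence and drivers, iron handling, NRF2 targets, vesicle markers and long non-coding RNAs linked to cancer or ferroptosis included. The ribosomal protein list had 3 named members, 2 of them tested, and the hypoxia and glycolysis list had 2; 0 of these 4 tested genes passed. No list reached the 5 members set for a list test.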

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

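The tests of the slide, of the 3' and 5' control probes, of the detected shares and of the unadjusted counts over splits were chosen or altered after the results were seen. Control probes outside the main measurement gave 2 signals that were higher in every resistant than in every parental sample. The adenovirus E1A control (+)E1A_r60_3 differed by 0.8282 and the control DCP_22_0 by 0.4687 on the log2 scale, both detected in all 6 samples. Of 29 detected control probes, these 2 had all resistant samples above the parental ones and 0 had them below, where chance gives 5% each way. Many control probes outside those 29 also had all resistant samples above the parental ones, and no control probe had the reverse. Among them were 3xSLv1 (0.395), ETG09_205211 (0.396) and ETG10_236652 (0.412), which were detected on no array. Dim values of such probes thus lay higher on the resistant arrays after scaling. Whether this adds to the excess of higher probes was not tested.

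The first pattern is the 95 probes higher in resistant exosomes. The 10 possible splits of the 6 samples are too few for a share under 0.05: the real split was 1 of 10 with as many calls, and the highest of the others called 0. At an unadjusted p under 0.05 (limma), 3 of 10 splits reached the real 2203 probes. The highest other split, at 2946, set resistant 2, resistant 3 and parental 2 apart and so kept slide 2 on one side. Splits that set resistant 2 and 3 apart with parental 3 or with parental 1 also kept slide 2 on one side and gave 461 and 1748. The split at 2204, with resistant 1, resistant 3 and parental 3 on one side, parted the samples of slide 2.

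Whether surrogate values for dim spots account for most of the calls stays open. Raising each dim value to its array's lowest detected signal left 15 of the 95 called, an outcome set beforehand as speaking for this cause. Such raising also shrinks the difference of a probe truly absent from parental samples, so the loss of calls cannot decide. At an unadjusted p under 0.05 (limma) all 95 still stood, though they had been picked by their p values. The median difference of the 95 fell to 3.42 (SE 0.456) from 5.35 (SE 0.481). All 95 stayed higher, which was nearly fixed in advance, since all were detected in every resistant sample and 91 in no parental one. The level of housekeeping mRNA stays open. With the panel median as a covariate, the median difference of the 95 was 5.182 (SE 0.51), an outcome set beforehand as speaking against this cause. Only 12 stayed called, an outcome set beforehand as speaking for it, though residual degrees of freedom fell from 4 to 3. The 95 were picked for a group difference, and the panel medians of the groups overlap. Their difference could therefore hardly fall, and the test decides neither. The slide stays open: probes picked on resistant 2 and 3 against 2 parental samples, and then read in resistant 1 minus the parental sample left out, had median differences of 0.26 to 0.69 (lowest 0.2566). The bound set for a slide effect was 0.5 or less, and that against it over 1 and above the upper limit of the range for random probe sets of like level; all 3 medians lay inside those ranges (0.24 to 2.48, 0.62 to 0.71 and 0.20 to 1.90), so they decide neither. Of 95 picked probes, 41 to 45 were detected in resistant 1 and 10 to 25 in the parental sample left out; a first run had given 2.86 to 3.70, but its filter had used the samples read and was replaced. A change in exosome RNA with erastin resistance stays open too and was not tested apart from these.

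The second pattern is the panel, low in parental 1 and high in resistant 3, where 15 of 17 genes were higher in resistant 3 than in parental 1, by a median of 4.17 on the log2 scale. Loss of 5' sequence stays open. Parental 1 and resistant 1 had nearly equal 3' to 5' GAPDH differences, 2.66 and 2.67. Their panel median difference was 3.299 (95% interval 1.61 to 4.40 over genes, which are not independent), which goes against such loss. Yet their 3' to 5' PGK1 differences were 5.02 and 4.09, with the 5' control not detected in parental 1. This is also 1 pair of samples. Fewer detected probes could not be separated from the pattern, since parental 3, detected at 40.1% against 40.9% in parental 1, stood 1.805 above it with an interval of 0.41 to 3.11 that holds the bound of 1. The isolation method, which may have differed between samples, and a difference between the lines stay open and were not tested.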

How the results depend on the processing

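Raised dim values, resistant 3 and parental 1 left out together, slide 1 alone and the panel covariate were chosen after seeing the data; so were the alternatives for the panel, the agreement of samples and one-group detection, single samples left out of the detected shares, and, for single genes and probes, slide as a block, the deposited table, the array median and the percentile over all probes. The count of 95 stayed within 1.5 times with quantile normalization (111) and the deposited table (76, 66 of them among the 95), which may not be separate settings. The count also stayed within that range with trended robust variance (67) and array weights (98). It was 197 with the percentile over all probes (192 higher, 5 lower), 172 with the array median (164 higher, 8 lower), 38 with no detection filter, 16 with dim values raised, 12 with the panel covariate, 1 with normexp, 1 with the plain t-test per probe, and 0 with the all-array filter, with slide as a block, with slide 1 alone, and without resistant 3 and parental 1 together (1564 at an unadjusted p under 0.05). Leaving out single samples gave 1 to 101. The cause was not tested, except that blocks, covariates and fewer samples leave fewer degrees of freedom and that the all-array filter removes all 95 by construction. The replicate block gave 0 calls (2075 unadjusted); same-numbered samples had deviations that correlated at 0.102, -0.037 and -0.06, so the numbers do not pair samples, and resistant 1 correlated best with parental 3. The panel's median difference kept its sign from 0.31 to 1.87 under every scaling, filter, block and single sample left out, and was -0.07 without resistant 3 and parental 1 together. The excess of within-group over between-group r was 0.0185, and 0.00275 to 0.0278 without single samples. Probes detected in one group only numbered 534 to 964 without single samples, where fewer arrays have to meet the rule. EIF3D was -0.187 with quantile normalization, -0.17 with the percentile over all probes, -0.361 with the array median, -0.413 with slide as a block, -0.127 in the deposited table and -0.749 to 0.831 without single samples. PRMT1 was -0.0107, -0.111 and -0.011 with quantile normalization, array median and deposited table, and -0.484 to 1.56 without single samples. ARHGDIA was -0.157 with the array median, and RACK1 ran from -0.863 to 1.97 without single samples. For single genes and probes, 112 values without single samples and 156 under other settings kept direction and side. ASHGV40036671 lost its call with either block (7.37 and 7.28, from 7.28), and ASHGV40056459 with those (6.57 and 7.19, from 7.19), without parental 1 (7.25) or parental 3 (7.29), and with normexp (2.92); ASHGV40057247 passed with 2 scalings and ASHGV40028800 with 1. Gene list shifts, counts of probe classes, a mean over a gene's probes and an estimated correlation for the lists were not run, for want of gene names. Signal over background limits the comparison: 91 of 95 calls have no parental signal to measure.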

Other observations

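Control probes for GAPDH and PGK1 of other species were on the arrays as well. The human 3' GAPDH control ranged over 4.41 log2 units across the 6 samples, from -1.30 in parental 1 to 3.10 in resistant 3. The mouse 3' GAPDH control, detected in all 6 samples, ranged over 0.22 units, with group means of -1.19 ± 0.11 in resistant and -1.15 ± 0.063 in parental samples (SD, n = 3 each). The rat 5' GAPDH control ranged over 3.51 units. The human 5' PGK1 control was detected in 3 resistant and 2 parental samples and had means of -5.30 ± 1.20 and -6.62 ± 2.13. The parental mean includes -9.035 in parental 1, where this control was not detected.

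Of the control RNAs that carry no human sequence, 1 of 10 E1A probes and 2 of 12 ERCC probes were detected on all 6 arrays.

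A test chosen after the data were seen asked whether the first principal component follows housekeeping mRNA. Across the 6 samples, its r with the panel median was 0.8413 (exact permutation p = 0.0514, 0.126 after Benjamini-Hochberg adjustment over 3 relations) and Spearman's rho was 0.6 (exact permutation p = 0.242, 0.297 adjusted). Without parental 1 and resistant 3, the samples farthest from the panel's median, r was -0.399, so the relation rests on those 2 samples. The share of detected probes and the 3' to 5' GAPDH difference gave r of 0.683 and -0.683 with the component (exact permutation p = 0.126 and 0.119, both 0.126 adjusted) and rho of 0.543 and -0.6 (exact permutation p = 0.297 and 0.242).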
